A study of Mus musculus with 30 samples.

How the data were processed

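Liver RNA from female C57BL/6 mice was measured on 2-colour Agilent mouse gene expression arrays, with 1 array per animal. Of the 30 arrays, 16 held liver RNA of control mice and 14 that of mice given 0.162 mg of Printex 90, a carbon black made of nanoparticles, into the trachea. The labels describe the control treatment only as none, and the series text speaks of 6 mice per treatment group, fewer than the arrays analysed here. On every array the liver RNA carried Cy5 and a universal mouse reference RNA carried Cy3, so no dye was swapped.

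The scanner files deposited for each array give foreground and background intensity per spot in both dyes, in arbitrary units as extracted by the authors with Agilent Feature Extraction. Of the arrays, 25 were extracted with version 10.7.3.1 and 5, on 2 slides, with version 10.1.1.1, per the file headers. A log10 ratio of the dyes also stands in these files, per the file headers. The value table deposited with the series holds log2 ratios of Cy5 over Cy3. This was checked on 15470 bright spots per array. Each column of that table matched its own array best in 30 of 30 cases, with r from 0.987 to 0.994 across spots and slopes from 0.972 to 0.983. The medians of its columns lay between -0.045 and -0.021.

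Median foreground signals were used, since the files analysed here hold no mean signal. Background was corrected by normexp with an offset of 50, and ratios were normalised within each array by loess with control spots at weight 0 (limma 3.58.1, R 4.3.3, data.table version 1.17.8). Spots the scanner software had marked as outliers were set to missing, which removed 924 probe values over 868 probes. Spots of the same probe were averaged, as 245 probes were printed 10 times. Of 41174 probes, 24375 received a gene symbol through their transcript accession, matched to a RefSeq table of the mouse genome build GRCm38.p6. The array design is older than that build, so no coordinates are given, and 3169 spot names differed between the 2 design versions. A probe was tested when Cy5 was well above background on at least 14 of 30 arrays, which left 23607 probes and 12188 named genes, while 6534 tested probes carry no symbol here. Each gene was represented by its tested probe with the highest mean Cy5 signal. The median Cy5 signal of an array lay between 104 and 196 and the share of probes well above background in Cy5 between 42.8% and 79.2%. The number of arrays limits the precision of all values.

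The arrays lay on 9 slides with 2 to 4 arrays each, scanned in 6 runs. Controls occupied positions 1 and 2 of a slide and exposed animals positions 3 and 4, so position and group are tied. Slide was a random block in all limma fits (correlation 0.159 in the pooled fit), and 7 slides held both groups. Animal numbers fall into 3 runs of neighbouring numbers in each group, where a gap of more than 10 starts a new run. Runs 1, 2 and 3 held 6, 5 and 5 control animals and 4, 5 and 5 exposed animals. The labels do not say what a run is, and in the planned tests no run of one group was matched to a run of the other. Later steps compared exposed runs with single control runs, and averaged runs of the same number over both groups for Cyp2b10 and Cyp2c55.

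Exposed and control animals were compared by the two-sided moderated test of limma, with Benjamini-Hochberg adjustment over all tested probes and a threshold of 0.05. Differences among the runs of a group were tested by the moderated F test of limma in a fit of 6 run means. Each exposed run was then compared with the mean of the 3 control runs, a step added after the differences among runs had been seen. The Cy3 channel, which holds the same reference RNA everywhere, was compared between the same array positions in the same way. Errors of differences are standard errors (SE) and errors of group means are standard deviations (SD).

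A set of 42 gene lists covering liver pathways, stress responses and cell type markers was tested with cameraPR at a preset correlation of 0.01. Tests with camera at an estimated correlation and fixed slides, with fry, and by exact permutation within slides (69984 arrangements) stand beside it. List scores, the mean log ratio over the members, were compared among runs by permutation (100000 resamples), adjusted over 84 tests, and the neutrophil score was tested again without Lcn2 after its values had been seen. Counts adjusted over the list alone use the Benjamini-Hochberg method within that list. Quality values and principal components were compared by two-sided permutation tests. A clock phase score, the mean of Dbp, Tef, Nr1d1, Nr1d2, Per2 and Per3 minus the mean of Arntl, Clock and Cry1 with each gene centred over all animals, was added after the third principal component had been examined.

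The groups, the tests, the gene lists and the rule for named genes were chosen before the data were examined. The rule names genes past the threshold (the 10 highest and 10 lowest, and up to 4 members of each list by smallest p) and a fixed set of 14 genes. Where fewer than 10 probes pass, it adds the 10 named genes with the smallest p. The same rule was applied to the comparisons of single runs. Other genes named were chosen after their values were seen. Some genes that the rule names are not reported here. Tested on simulated data with the observed spread and slide correlation, the pooled fit recovered 95.5% of 67 probes shifted by 0.6 log2 and the fit of exposed run 1 85.1%, with 6 false calls each. At 0.3 log2 the shares were 58.2% and 22.4%. Simulated probes were drawn independently of each other and without run structure beyond the added shifts, so these rates need not hold for the real arrays. Alternatives covered background correction, normalisation, filter, blocking, weights, Agilent's processed signals, the deposited value table, the list tests and leaving out animals or slides.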

Results

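Liver gene expression was measured in 16 control mice and in 14 mice that had received 0.162 mg of carbon black nanoparticles (Printex 90) through the trachea, with 1 array per mouse. The comparison asks whether particles deposited in the lung are followed by changes in liver RNA. All values are log2 ratios of liver RNA over the common reference RNA. The median Cy5 signal per array ranged from 104 to 196, the median Cy3 signal from 43 to 113, and 42.8% to 79.2% of probes were well above background in Cy5. None of these measures differed between the groups by permutation (adjusted p = 0.753 for both median signals), whereas slide accounted for 89.5% of the variance of the median Cy5 signal. Correlations between pairs of arrays lay between 0.937 and 0.991. Animal numbers fall into 3 runs of neighbouring numbers in each group, called control or exposed runs 1, 2 and 3 here, and the labels do not say what a run is. Control runs held 6, 5 and 5 animals and exposed runs 4, 5 and 5. Each group used a pair of neighbouring positions on a slide, and all animals of run 1 lay in the first position of their pair and all animals of run 3 in the last, in both groups.

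Over all animals, Eif4ebp3 and Dhrs1 were the named genes that rose in the livers of exposed mice, and no named gene fell. Eif4ebp3 (NM_201256), which encodes a repressor of translation that binds the initiation factor eIF4E, rose by 0.70 ± 0.12 on the log2 scale (SE; 1.62-fold; limma adjusted p = 0.0127). Its mean log ratio was 0.38 ± 0.22 (SD, n = 16) in controls and 1.06 ± 0.47 (SD, n = 14) in exposed mice, and it was higher in exposed mice on 7 of 7 slides holding both groups. A second Eif4ebp3 probe rose by 0.71 ± 0.11 (adjusted p = 0.0113). Dhrs1 (NM_026819), a short-chain dehydrogenase, rose by 0.24 ± 0.05 (1.18-fold; adjusted p = 0.0366), also on 7 of 7 slides. The probe A_51_P267587, which has no gene symbol here, rose by 0.59 ± 0.10 (adjusted p = 0.0146). In total 4 of 23607 probes passed, all upward, and 2875 had an unadjusted p under 0.05 where 1180 would be expected by chance. Probes are not independent of each other, so this count alone does not show an effect of exposure. The reference RNA in Cy3 gave 1533 in the same comparison. With 6 run means 48 probes were higher and 17 lower, and with array weights 88 higher and 57 lower. With a clock phase score as a covariate no probe passed, with Eif4ebp3 at 0.68 ± 0.14 (adjusted p = 0.187) Dhrs1 at 0.27 ± 0.05 (adjusted p = 0.179) and A_51_P267587 at 0.38 ± 0.10 (adjusted p = 0.979). With slide as a fixed block A_51_P267587 stood at 0.58 (adjusted p = 0.198). The Dhrs1 call ended under 29 of 57 alternatives, that of A_51_P267587 under 10 and that of Eif4ebp3 under 4. Leaving out control animals 549, 551, 573, 574 and 600 gave 24, 37, 111, 14 and 11 probes, and leaving out exposed animals 176, 177, 179, 195 and 197 gave 41, 8, 7, 2 and 15.

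Among genes that did not pass, the smallest p belonged to Zrsr2 at 0.32 (adjusted p = 0.0522), although its other probe gave -0.09. Sox9, a transcription factor of bile duct cells, stood at -0.45 ± 0.09 (adjusted p = 0.0651) and the immediate early gene Ier5 at -0.48 ± 0.10 (adjusted p = 0.0702), each lower on 7 of 7 slides. Both passed downward with 6 run means (adjusted p = 0.0474 each), and so did Zbtb5 (adjusted p = 0.0474). Lpin2, a phosphatidate phosphatase, stood at 0.52 ± 0.11 (adjusted p = 0.0702) and Wipi1, an autophagy gene, at 0.41 ± 0.09 (adjusted p = 0.0768). Zbtb5, Rhbdd2, N4bp3, Cpsf4l and Gins3 completed the 10, with differences of -0.27, 0.34, -0.35, 0.89 and -0.23. None of the 13 measured genes named in advance from the exposure passed. The acute phase genes Saa1, Saa2 and Orm2 stood at 0.00 ± 0.19, -0.13 ± 0.11 and 0.00 ± 0.11, and Saa3 and Lcn2 at 0.52 ± 0.49 (adjusted p = 0.719) and 0.61 ± 0.46 (adjusted p = 0.627). Over the alternatives Saa3 ranged from -0.45 to 0.81 and Lcn2 from -0.34 to 0.84. The squalene epoxidase Sqle, of cholesterol synthesis, stood at 0.39 ± 0.14 (adjusted p = 0.248). Cyp7a1, the rate-limiting enzyme of bile acid synthesis, stood at 0.37 ± 0.34, and the cholesterol exporter Abca1 at -0.05 ± 0.07. The metallothioneins Mt1 and Mt2 stood at 0.09 ± 0.22 and 0.27 ± 0.45, and heme oxygenase Hmox1 at -0.10 ± 0.09. Cyp1a1, a target of the aryl hydrocarbon receptor, was well above background on 5 of 30 arrays and was not tested.

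At the level of gene lists, 6 of 42 differed between all exposed and all control mice with the preset correlation. Other regroupings of the arrays gave a median of 8 lists by this test, so its p values do not exclude chance. Cholesterol synthesis genes were higher in exposed mice, with a median of 0.23 over 25 members (adjusted p = 2.79e-10), 12 of them higher when adjusted over the list alone and 0 over all probes. Among these 12, Lss stood at 0.65 ± 0.16, Mvk at 0.46 ± 0.13 and Fdps at 0.37 ± 0.10. Interferon response genes were lower with a median of -0.20 over 33 members (adjusted p = 4.18e-07), 1 of them when adjusted over the list alone. Rsad2, which is not that member, stood at -0.46 ± 0.19. Glucocorticoid and fasting genes were higher with a median of 0.10 over 24 members, 5 of them adjusted over the list alone, which include Klf9 at 0.58 ± 0.16 and Fkbp5 at 0.84 ± 0.26. Circadian clock genes had a median of 0.32 over 20 members, with 7 higher and 3 lower when adjusted over the list alone. Cholangiocyte markers (10 members, Sox9 among them) and cell cycle genes (32 members) had medians of -0.13 and -0.08. All 6 calls were lost, each at adjusted p = 0.928 with an estimated correlation, with a smallest adjusted p of 0.25 by fry and of 0.573 by exact permutation within slides. Without the exposed animals of run 1 the medians of the cholesterol, interferon, cell cycle and clock lists were 0.12, -0.03, 0.00 and 0.24, and these lists no longer passed.

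The first 2 principal components (18.6% and 14.5% of the variance) showed no group difference (permutation p = 0.621 and 0.637, adjusted p = 0.753 each). On the third principal component (8.33% of the variance) exposed animals were higher by 15.4 units, and by 14.2 within slides, on 7 of 7 slides. Exact permutation within slides gave p = 0.000514 for it (adjusted p = 0.00257 over 5 measures, which left out the first 2). Dbp, a transcription factor at the output of the circadian clock, had the largest absolute loading of all tested probes on that component, and Tef, Nr1d2 and Arntl were above the 99.8 percentile. A clock phase score, built from these and other clock genes after the component had been seen, was -0.44 ± 0.92 (SD, n = 16) in control and 0.51 ± 0.69 (SD, n = 14) in exposed animals, and no p is given for it because its genes were chosen from the data. Its means were 0.45, -0.02 and 1.08 in exposed runs 1, 2 and 3 and -0.17, -0.40 and -0.83 in the control runs. The score of the clock list, chosen beforehand, was 0.72, 0.35 and 0.79 in the exposed runs (permutation p = 0.0207, adjusted p = 0.137) and 0.40, 0.33 and 0.26 in the control runs (permutation p = 0.573, adjusted p = 0.777). Dbp stood at 1.02 ± 0.36, Tef at 0.76 ± 0.21 and Nr1d2 at 0.62 ± 0.17, against -0.74 ± 0.23 for Arntl and -0.68 ± 0.19 for Nfil3, and none of these passed over all probes (adjusted p from 0.146 to 0.236).

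**Figure D1:**
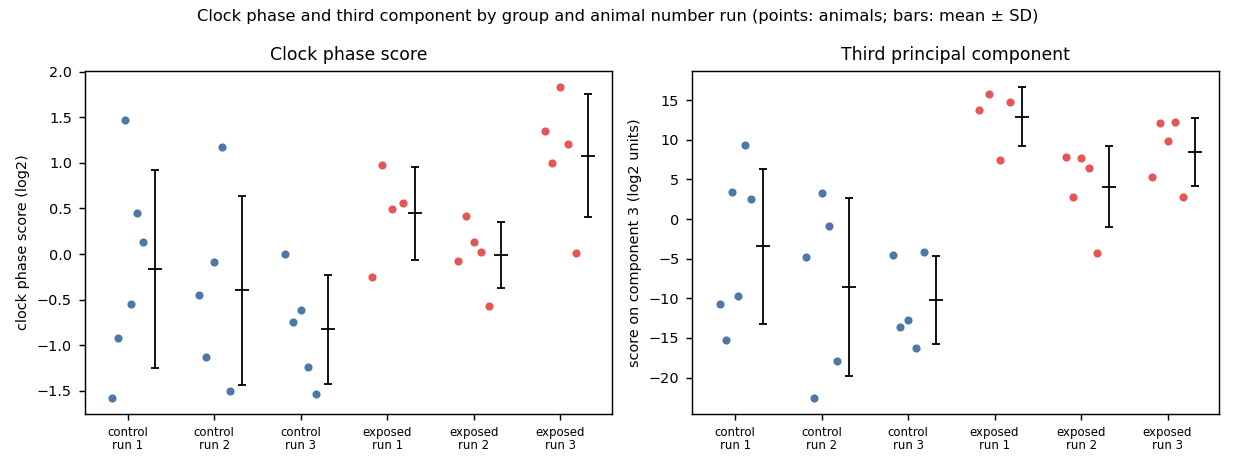
Clock phase score (left, log2) and score on the third principal component (right, log2 units) of each animal, by group and animal number run, with points for animals and bars for mean ± SD. Exposed animals averaged 0.51 on the phase score and control animals -0.44, and both groups overlap.

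The common reference RNA in Cy3, which is the same on every array, differed at 2 of 23607 probes between the positions used by exposed and control animals, 1 higher and 1 lower (1533 with an unadjusted p under 0.05). Without background correction or without the slide block, limma called 0 probes. The first 3 principal components of the reference channel gave permutation p values of 0.353, 0.429 and 0.0511 for the group difference (adjusted p = 0.429, 0.429 and 0.0852). Within slides the exact permutation p values were 0.493, 0.0336 and 0.164 (adjusted p = 0.0559 for the component with 0.0336, which was higher in exposed animals on 2 of 7 slides).

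Within the exposed group Lcn2, Saa3, Lss and Usp18 differed between the animal number runs. Between the 3 exposed runs 976 probes differed (720 named genes; limma F test), against 21 probes (14 named genes) between the 3 control runs. Lcn2, the iron-binding lipocalin secreted by neutrophils and by hepatocytes in the acute phase, had mean log ratios of 3.64 ± 0.41 (SD, n = 4), 0.56 ± 0.28 (n = 5) and 0.17 ± 0.88 (n = 5) in exposed runs 1, 2 and 3 (limma adjusted p = 0.000107). Saa3, an acute phase serum amyloid, had means of 2.88 ± 1.18, -0.23 ± 0.34 and -0.67 ± 0.70 (adjusted p = 0.00115). The lanosterol synthase Lss had means of 2.59 ± 0.27, 1.45 ± 0.34 and 1.74 ± 0.35 (adjusted p = 0.0108) and the interferon-induced Usp18 means of -1.31 ± 0.27, -0.02 ± 0.40 and -0.35 ± 0.15 (adjusted p = 0.000303). The score of the whole acute phase list was 3.62 ± 0.18 (n = 4), 3.28 ± 0.20 and 3.32 ± 0.26 in these runs (permutation p = 0.0937, adjusted p = 0.303). Run 1 differed from run 2 at 1402 probes and from run 3 at 467, while runs 2 and 3 differed at 8. With the array position as an added term 164 probes differed between exposed runs, and with slide as a fixed block 172. Without exposed animals 176, 177, 180, 195 and 196 in turn the count was 419, 598, 645, 640 and 633.

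In the livers of the 4 mice of exposed run 1, genes of cholesterol synthesis and several acute phase and drug metabolism genes rose and interferon response genes fell against the mean of the 3 control runs. The steepest rises were those of Lcn2 (3.02 ± 0.38; 8.11-fold; limma adjusted p = 4.35e-05), Saa3 (2.95 ± 0.48; 7.71-fold; adjusted p = 0.00054) and the estrogen sulfotransferase Sult1e1 (2.69 ± 0.49; 6.45-fold; adjusted p = 0.00157). Cyp2b10, a cytochrome P450 controlled by the receptor CAR, rose 3.99-fold (adjusted p = 9.9e-05) and Derl3, a factor of endoplasmic reticulum associated degradation, rose by 1.61 ± 0.30. The peroxisomal oxidase Hao2 fell by 1.86 ± 0.50 (adjusted p = 0.0281), Scd1, the stearoyl-CoA desaturase, by 1.28 ± 0.21, and Ifi27l2a by 1.32 ± 0.18. Without exposed animal 180 Hao2 stood at -1.21 (adjusted p = 0.208), and with slide as a fixed block at -1.92 (adjusted p = 0.0652). Altogether 1132 probes differed, 378 up and 754 down, with 843 named genes among them. The split into higher and lower probes depended on the scaling and on animal 176, with 978 up and 1003 down from the processed Agilent signals, 820 up and 827 down in the deposited value table, 128 up and 46 down after median centring, and 346 up and 189 down without animal 176, which had the value 44.4 on the first principal component. Control run 1 resembled exposed run 1 most: against it alone 58 probes passed (31 up, 27 down), all among the 1132, against 903 with control run 2 and 894 with control run 3. Without exposed animal 177 the count was 480, and it was 288 with array position as a term, 431 with slide as a fixed block and 444 with the clock phase score.

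Of the 25 measured cholesterol synthesis genes 14 rose in exposed run 1, 0 fell and 11 did not pass, with 19 higher when adjusted over the list alone and a median of 0.63. Lss rose by 1.37 ± 0.19 (2.59-fold; adjusted p = 0.000122), the lanosterol demethylase Cyp51 by 1.07 ± 0.15 (2.10-fold) and mevalonate kinase Mvk by 1.03 ± 0.14. The list passed with the preset correlation (adjusted p = 9.74e-26) and with fry (adjusted p = 0.00122), and had adjusted p = 0.117 with an estimated correlation. Against control run 1 alone 5 of the 25 members passed, these 3 among them at 1.31, 0.78 and 0.91, while Sqle at 0.81 (adjusted p = 0.0888), Hsd17b7 at 0.60 (adjusted p = 0.149) and Tmem97 at 0.27 (adjusted p = 0.175) did not. Between the exposed runs the list score was 2.78 ± 0.16 (SD, n = 4) in run 1, 2.17 ± 0.26 in run 2 and 2.48 ± 0.20 in run 3 (permutation p = 0.00706, adjusted p = 0.102).

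Genes of the interferon response moved the other way, with 20 of 33 members lower in exposed run 1, 0 higher and 13 that did not pass (27 lower when adjusted over the list alone; median -0.54). Usp18, a brake on interferon signalling, fell by 1.05 ± 0.14 (adjusted p = 9.9e-05), the guanylate-binding protein Gbp3 by 1.14 ± 0.17, the antiviral Rsad2 by 1.16 ± 0.23, and Bst2 by 0.83 ± 0.12. The chemokine Cxcl9 fell by 1.28 ± 0.35 (adjusted p = 0.0325), but stood at -0.03 (adjusted p = 0.974) with the processed Agilent signals and at -0.81 (adjusted p = 0.252) without exposed animal 176. The list had adjusted p = 0.178 with an estimated correlation and adjusted p = 0.00038 with fry. With control run 1 as the only control 2 of 33 members passed and the median was -0.34: Usp18 and Bst2 fell by 0.73 and 0.61, while Gbp3 at -0.72 (adjusted p = 0.127) and Rsad2 at -0.73 (adjusted p = 0.259) did not pass. Between exposed runs the list score was 0.51 ± 0.21 (n = 4), 1.14 ± 0.28 and 0.92 ± 0.11 (permutation p = 0.00128, adjusted p = 0.0538).

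**Figure D2:**
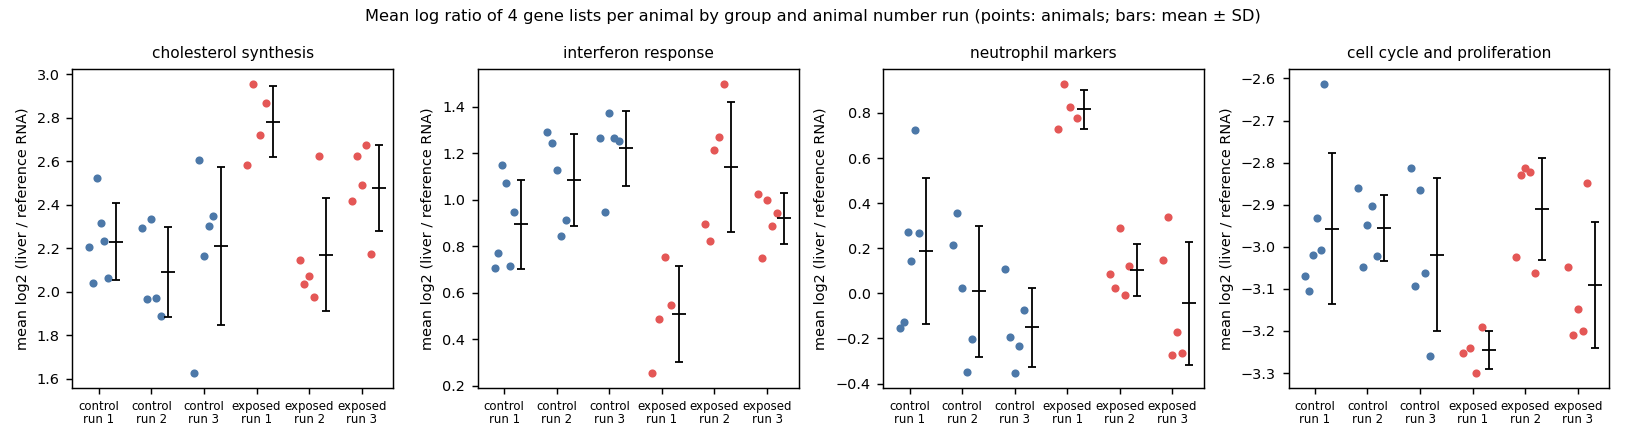
Mean log2 ratio over the members of the cholesterol synthesis, interferon response, neutrophil marker and cell cycle lists in each animal, by group and animal number run, with points for animals and bars for mean ± SD. Exposed run 1 had the highest mean for cholesterol synthesis (2.78) and neutrophil markers (0.82) and the lowest for the interferon response (0.51).

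Of the 6 measured neutrophil markers, Lcn2 and Chil3 (0.76 ± 0.17) rose in exposed run 1 and 4 did not pass, S100a8 at 0.27 and S100a9 at 0.65 among them. Lcn2 is also a member of the acute phase list, in which Lcn2, Saa3 and Serpina3n (0.64 ± 0.16) rose and 35 of 38 members did not pass, Saa1 at 0.69 ± 0.24 (-0.01 by its other probe) and Saa2 at -0.49 ± 0.15 (adjusted p = 0.0605) among them. The neutrophil list had adjusted p = 0.117 with an estimated correlation and the acute phase list adjusted p = 0.870. With fry they had adjusted p = 0.000384 and 0.312. Between exposed runs the neutrophil score was 0.82 ± 0.09 (n = 4), 0.10 ± 0.12 and -0.04 ± 0.27 (permutation p = 0.00042, adjusted p = 0.0353), the lowest adjusted p of the 84 list scores. Without Lcn2 the score of the other 5 members was 0.25 ± 0.12 (n = 4), 0.01 ± 0.10 and -0.09 ± 0.20 (permutation p = 0.0199, not adjusted). Lcn2 also varied in control run 1, with a mean of 1.65 ± 1.21 (SD, n = 6) against 0.23 ± 0.54 and 0.04 ± 0.18 in control runs 2 and 3. Against control run 1 alone Lcn2 rose by 2.03 (adjusted p = 0.0374), while Saa3 at 2.08 (adjusted p = 0.102), Chil3 at 0.58 (adjusted p = 0.214) and Serpina3n at 0.41 (adjusted p = 0.395) did not pass. Serpina3n stood at 0.15 (adjusted p = 0.785) with the processed Agilent signals.

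**Figure D3:**
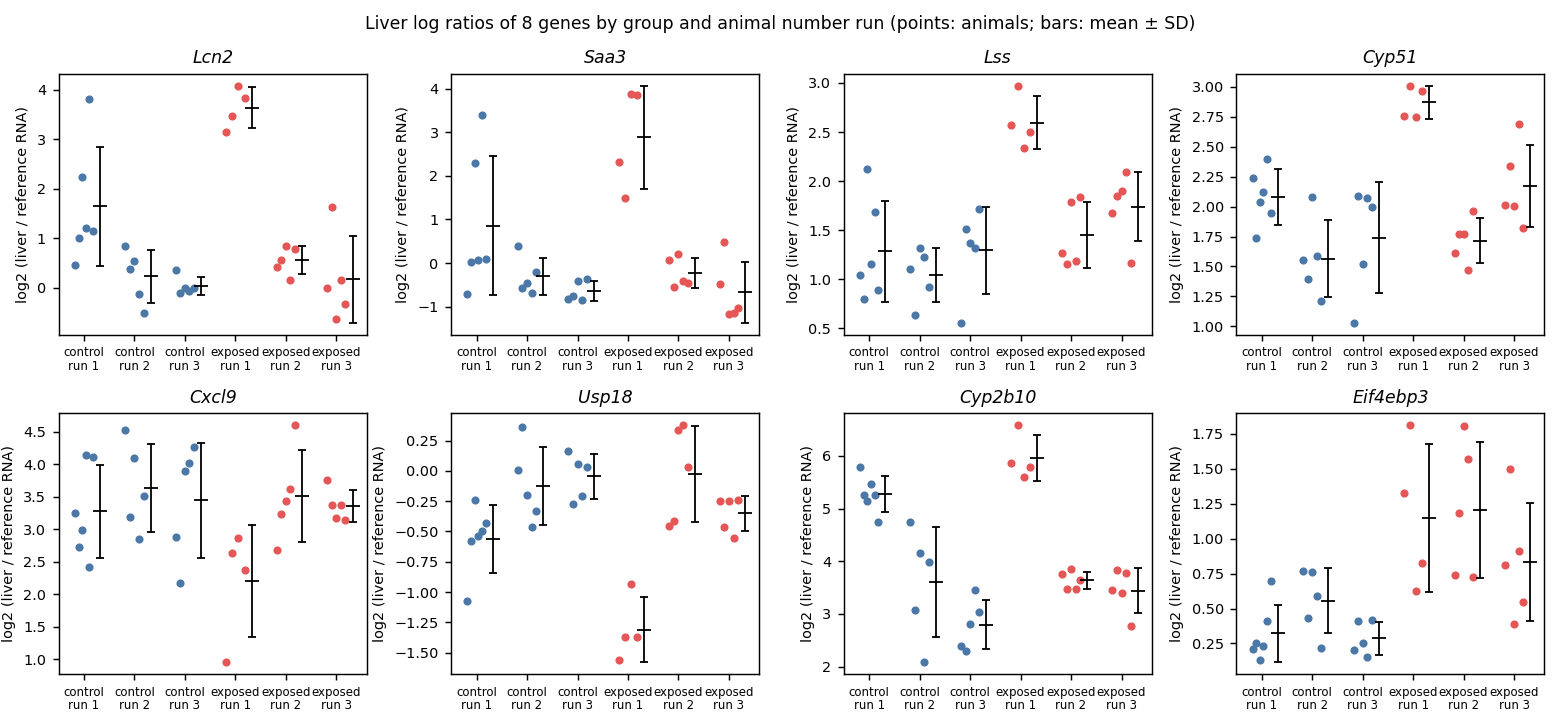
Log2 ratio of liver over reference RNA of 8 genes in each animal, by group and animal number run, with points for animals and bars for mean ± SD. Lcn2 averaged 3.64 in exposed run 1 and 1.65 in control run 1, and Cyp2b10 averaged 5.96 and 5.28 in these runs.

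Among xenobiotic enzymes 6 of 38 members rose in exposed run 1 and 32 did not pass. They include Sult1e1, Cyp2b10, the retinal dehydrogenase Aldh1a1 (0.90 ± 0.11; adjusted p = 2.53e-05) and Por, the electron donor of microsomal P450 enzymes (0.79 ± 0.16). The list had adjusted p = 0.932 with an estimated correlation. Against control run 1 alone Aldh1a1 rose by 0.67 (adjusted p = 0.0213), whereas Sult1e1 stood at 2.09 (adjusted p = 0.112), Cyp2b10 at 0.68 (adjusted p = 0.373) and Por at 0.53 (adjusted p = 0.225). Cyp2b10 stood at 0.77 (adjusted p = 0.256) with the processed Agilent signals. Of 30 NRF2 genes Ugdh rose by 0.78 ± 0.12, Gsta4 fell by 0.63 ± 0.11 and 28 did not pass, with no call for the list. Neither passed against control run 1 alone, Ugdh at 0.54 (adjusted p = 0.0924) and Gsta4 at -0.54 (adjusted p = 0.0766), and Gsta4 did not after median centring (adjusted p = 0.172). Of the fatty acid synthesis genes Scd1 and Elovl5 (-0.73 ± 0.13) fell, and of 25 members 1 rose, 4 fell and 20 did not pass, with no call for the list. The apolipoprotein Apoa4 rose by 1.05 ± 0.23, but stood at 0.50 (adjusted p = 0.505) with the processed Agilent signals. Against control run 1 alone Scd1 at -0.94 (adjusted p = 0.0804), Elovl5 at -0.42 (adjusted p = 0.264) and Apoa4 at 0.74 (adjusted p = 0.251) did not pass. Transthyretin, Ttr, fell by 1.14 ± 0.25 with loess ratios but stood at 0.58 with the processed Agilent signals.

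Of the 32 cell cycle genes 7 fell in exposed run 1, 1 rose and 24 did not pass. Stmn1 fell by 0.96 ± 0.14 (adjusted p = 0.000239), the ribonucleotide reductase subunit Rrm1 by 0.49 ± 0.07 and the replication helicase subunit Mcm7 by 0.43 ± 0.08, while the thymidine kinase Tk1 rose by 0.35. The list had adjusted p = 0.823 with an estimated correlation and adjusted p = 0.0133 with fry. Of 20 immediate early genes Myc rose by 0.95 ± 0.19 (adjusted p = 0.00334), Jund fell by 0.47 ± 0.11 and 18 did not pass. Stmn1, Rrm1 and Myc also passed against control run 1 alone, at -0.95, -0.43 and 1.05, while Mcm7 at -0.37 (adjusted p = 0.0766) and Jund at -0.32 (adjusted p = 0.331) did not. Among cell type markers, 4 of 22 of Kupffer cells and macrophages fell, such as Lyz2 by 0.72 ± 0.16 and Ctss by 0.59 ± 0.13, and 3 of 9 of monocytes and dendritic cells, such as Cd74 by 0.70 ± 0.15 and H2-Ab1 by 0.61 ± 0.15. Of 17 endothelial markers Cd34 and Eng fell, by 0.48 ± 0.12 and 0.34 ± 0.10, and of 15 stellate cell and fibroblast markers 3 fell, Col3a1 by 0.98 ± 0.19 among them. With control run 1 as the only control Col3a1 fell by 1.03 (adjusted p = 0.0382), while Lyz2, Ctss, Cd74, H2-Ab1, Cd34 and Eng did not pass, at -0.53, -0.32, -0.51, -0.48, -0.53 and -0.28. These macrophage, monocyte and endothelial lists had adjusted p = 0.823, 0.823 and 0.870 with an estimated correlation, and the stellate cell list did not pass with the preset one (adjusted p = 0.0957). With fry the macrophage, monocyte and endothelial lists had adjusted p = 0.0692, 0.0147 and 0.102. After median centring Stmn1, Rrm1, Mcm7, Jund, Lyz2, Ctss, Cd74, Cd34 and Eng did not pass, at -0.79, -0.34, -0.24, -0.18, -0.48, -0.41, -0.58, -0.30 and -0.25, and nor did Col3a1 at -0.80 (adjusted p = 0.0552), Tef at 1.27 (adjusted p = 0.0531), Per3 at 0.52 (adjusted p = 0.144) and Usp2 at 1.18 (adjusted p = 0.121). Col3a1 also did not pass without animal 176 (adjusted p = 0.0506), with array position as a term (adjusted p = 0.0857) or against control run 3 alone (adjusted p = 0.0581). Of the clock list Tef (1.06 ± 0.27), Per3 (0.61 ± 0.15) and Usp2 (1.18 ± 0.34) rose and 17 of 20 did not pass. The clock list had adjusted p = 0.178 with an estimated correlation and adjusted p = 0.0133 with fry. Of the unfolded protein response Derl3 rose and 23 of 24 did not pass (adjusted p = 0.823 with an estimated correlation, 0.217 with fry). Derl3 stood at 0.76 (adjusted p = 0.376) against control run 1 alone. Tef at 0.70 (adjusted p = 0.375), Per3 at 0.40 (adjusted p = 0.347) and Usp2 at 1.10 (adjusted p = 0.256) did not pass in that comparison either. The Usp2 call ended under 21 alternatives, 13 of which left out a single animal. The median of 43 oxidative phosphorylation genes was -0.16 (2 lower, Uqcrh and Cox5a) but 0.17 after median centring and 0.03 with the processed Agilent signals, so its direction depended on the scaling, and the list had adjusted p = 0.988 with an estimated correlation. The Cox5a call ended under 24 alternatives, 16 of which left out a single animal, and the Uqcrh call under 13, with 5 such cases.

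Exposed run 3 differed from the mean of the control runs at 31 probes, 26 up and 5 down, and exposed run 2 at 4 probes, all up. In run 3 Lpin2 rose by 0.87 ± 0.14 (limma adjusted p = 0.0145), the nucleobase transporter Slc43a3 by 0.72 ± 0.13, the cholesterol synthesis enzyme Hsd17b7 by 0.67 ± 0.14 and Dhrs1 by 0.32 ± 0.06. The transporter Slc16a6 fell by 0.70 ± 0.13 and Tmem45a by 0.45 ± 0.08. Of the 25 cholesterol synthesis genes 1 rose in run 3, with 10 higher when adjusted over the list alone and a median of 0.29. That list passed with the preset correlation (cameraPR adjusted p = 3.25e-08), but not with fry (adjusted p = 0.315) or an estimated correlation (adjusted p = 0.882). In run 2 its median was -0.02. Of the 20 clock genes 0 passed over all probes in run 3, with 11 higher and 3 lower when adjusted over the list alone and a median of 0.49 (fry adjusted p = 0.0078; adjusted p = 0.776 with an estimated correlation). In run 2 Apbb3 rose by 0.62 (adjusted p = 0.0221). With the clock phase score or array position as a covariate 0 probes passed in run 3 (limma, against 3089 with an unadjusted p under 0.05 without it), and without single animals its count ranged from 0 (without exposed animal 213 or 215) to 137 (without control animal 573). For run 2 that range was 0 (without exposed animal 195) to 67 (without control animal 573). With slide as a fixed block 0 probes passed in run 2 and 0 in run 3.

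Cyp2b10 and Cyp2c55, members of the cytochrome P450 family, were highest in run 1 among the control runs. Cyp2b10 had mean log ratios of 5.28 ± 0.35 (SD, n = 6), 3.61 ± 1.04 (n = 5) and 2.80 ± 0.47 (n = 5) in control runs 1, 2 and 3 (limma adjusted p = 0.000207), and Cyp2c55 means of 0.59 ± 0.60, -0.85 ± 0.18 and -1.06 ± 0.46 (adjusted p = 0.00163). In exposed runs 1, 2 and 3 Cyp2b10 averaged 5.96 ± 0.43, 3.64 ± 0.17 and 3.44 ± 0.42, and Cyp2c55 0.36 ± 0.69, -1.32 ± 0.28 and -1.34 ± 0.14. The heat shock protein Hspb1 (adjusted p = 0.00753), the lipoprotein lipase Lpl (adjusted p = 0.0222) and the retinol saturase Retsat (adjusted p = 0.0234) also differed between control runs. By representative probe 13 genes differed between control runs and 633 between exposed runs, and 9 were shared, Cyp2b10, Cyp2c55, Retsat and Entpd5 among them. Independent tests would share 0.675 (Fisher's exact test p = 1.54e-09). Both F tests come from 1 fit and share each probe's residual variance, and genes are not independent. That p therefore cannot show that the overlap exceeds expectation. With slide as a fixed block 3 probes differed between control runs and with array position as a term 12. Without control animals 547, 551, 572, 575, 596 and 599 in turn the count was 13, 12, 9, 13, 10 and 11.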

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

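The fits with the clock phase score, without animal 176 and without the exposed animals of run 1, the comparisons of single exposed runs, the regrouping examined at the end and all tests of Cyp2b10 and Cyp2c55 are tests chosen only after the result was seen.

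The difference between exposed runs in 976 probes stands out because animals of the same group differ under the same contrast, and so do Lcn2 (limma adjusted p = 0.000107) and Saa3 (limma adjusted p = 0.00115). Array position as the whole cause is argued against for the 467 probes that separate runs 1 and 3. Within exposed run 2, which used both positions, they differed by -0.0142 on the log2 scale between positions (95% interval -0.135 to 0.107), far from the 0.589 between runs 1 and 3. The choice of these probes can inflate the 0.589, and the 2 and 3 arrays compared within run 2 shared no slide. With position as an added term, which is tied to runs 1 and 3, 164 probes differed instead of 976. A part played by position therefore stays open. A single array apart from the others is argued against by the 419 probes that differed without animal 176. In Cy3 5 probes differed between exposed runs, which gives no sign of a hybridisation difference that also reaches the reference channel. That limma F test had 629 probes with an unadjusted p under 0.05 where 1180 would be expected. Its count may thus run low and cannot be set against the 976 as like for like. The Cy3 values were quantile normalised between arrays, and a difference confined to Cy5 would not show there and was not tested. Of 100 regroupings of the exposed animals 1, the real one, gave as many probes, and the highest of the others gave 5. This argues against chance, although the regroupings ignored the slides. What the runs stand for is not given in the sources used here, so no biological explanation was tested, and the likeness of control run 1 to exposed run 1 stays open.

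The cholesterol synthesis list was higher in exposed animals by 0.23 on the log2 scale with slides fixed (95% interval 0.02 to 0.45), a call lost at adjusted p = 0.928 with an estimated correlation and at adjusted p = 0.573 by exact permutation within slides. A position effect that also reaches the reference channel is argued against there, where the list shifted by 0.0301 (95% interval -0.0178 to 0.0781). A position effect confined to Cy5 was not tested. With the clock phase score as a covariate the difference was 0.159 (95% interval -0.0873 to 0.405), which includes both 0 and the full difference, so the list and clock phase cannot be told apart with these animals. Without the exposed animals of run 1 the difference was 0.0930 (95% interval -0.115 to 0.301). That interval also includes both 0 and the full difference, so this fit cannot tell whether run 1 carries most of it. The hypothesis about run 1 was found and tested on the same data. Against the mean of the control runs the list median was 0.63, -0.02 and 0.29 in exposed runs 1, 2 and 3. An effect of the particles stays among the open explanations, as untested.

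Cyp2b10 and Cyp2c55 were higher in run 1 than in run 3 of both groups, by 2.09 on the log2 scale on average. Array position would need the first position to be higher within run 2, where the difference was -0.575 (95% interval -1.03 to -0.118). In the reference channel both genes differed by 0.379 (95% interval 0.179 to 0.579) between these runs, well short of 2.09 and of the sign that lowers the ratio. No label gives the runs a meaning, so no biological explanation was tested.

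The other counts were set against 100 regroupings each, the real one included. For the pooled probe count 2 regroupings gave as many as the real 4 (highest other 13), and for the reference channel 3 gave as many as the real 2 (highest other 14). Neither result excludes chance, since the regroupings ignored the slides and the counts tested were not adjusted for each other. The regroupings also do not separate group from array position. The pooled count was 0 without slide 3, and the reference channel count was 0 without background correction or without the slide block. For the pooled lists 76 gave as many as the real 6 (median of the others 8, highest other 18), so chance cannot be excluded. The p values at the preset correlation therefore do not set a list apart from chance on their own. Lists of single exposed runs were not regrouped. Between control runs 1 gave as many as the real 21 (highest other 3), which argues against chance within these limits. For exposed run 1 against controls 1 gave as many as the real 1132 (highest other 93), which argues against chance within the same limits. For exposed run 3, 4 gave as many as the real 31 (highest other 73). For exposed run 2, 6 gave as many as the real 4 (highest other 177). Chance cannot be excluded for runs 2 and 3. The regrouping that called 177 probes against the real 4 points to a structure of the samples. It joined 1 animal of exposed run 2 with 1, 1 and 2 animals of control runs 1, 2 and 3, all from different slides, and the cause of its count was not tested.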

How the results depend on the processing

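Alternatives with the clock phase score, with single control runs, with exact permutation of the lists and without the exposed animals of run 1, as well as all those for single exposed runs, were chosen after seeing the data. Where a count moved, the cause was not tested unless stated. No paired analysis was possible because control and exposed animals share no replicate numbers, so they were matched by slide only. The 4 pooled probes became 65 with run means, 145 with array weights, 0 with the clock phase score, 0 after median centring, 17 without background correction, 17 in the deposited value table and 37 without the exposed animals of run 1. They became 2 in each of the smaller or less powered fits: the 7 slides with both groups, slide as a fixed block, and without the slides of the older protocol. Leaving out a slide gave 0 to 14, and leaving out an animal 2 to 111. In the pooled fit by limma 2875 probes had an unadjusted p under 0.05. Other alternatives gave 3 to 5. The 6 pooled lists became 0 with an estimated correlation, 0 with fry, 0 by exact permutation within slides and 14 after median centring, and ranged from 5 to 9 elsewhere (5 without exposed animal 176). The 976 probes between exposed runs became 164 with array position as a term and 172 with slide as a fixed block, and 419 to 1177 without single animals. The 21 between control runs became 12 and 3 in these fits, and 9 to 25 without single animals. The 2 reference channel probes became 0 without background correction and 0 without the slide block.

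For exposed run 1 the 1132 probes became 1981 with the processed Agilent signals, 288 with array position, 444 with the clock phase score, 58 against control run 1, 174 after median centring and 431 with slide as a fixed block, and 480 to 1412 without single animals. For run 2 the 4 probes became 0 with the processed Agilent signals, 153, 0 and 1 against control runs 1, 2 and 3, 0 with the stricter filter, 2 after median centring, 0 with slide as a fixed block and 2 in the deposited table, and 0 to 67 without single animals. For run 3 the 31 probes became 3 with the processed Agilent signals, 0 with array position, 0 with the clock phase score, 2 against control run 3, 1 after median centring, 15 without a filter, 4 without the slide block and 0 with slide as a fixed block, and 0 to 137 without single animals. Ttr reversed to 0.58 with the processed Agilent signals, and Uqcrh and Cox5a to 0.091 and 0.019 after median centring. Of the other values of named genes over all alternatives, 1342 pooled values kept their call or lack of one, 43 lost it and 95 gained one. Some of the 1342 changed sign without passing, as Saa3 did, with pooled values from -0.445 to 0.813. For exposed run 1, 2356 kept direction and call and 366 lost the call. Of 65 calls in exposed run 1, 50 ended against control run 1 alone. Signal over background limits the test to 23607 of 41174 probes.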

Other observations

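The lists below are part of the set chosen before the data were examined. Blood cell markers showed no list call over all animals: the 6 neutrophil markers had a median of 0.14 (adjusted p = 0.127) with 2 higher when adjusted over the list alone, and the 9 erythroid markers had a median of -0.07, with 2 lower when adjusted over the list alone, Slc4a1 at -0.22 ± 0.07 among them, and none over all probes. The 9 B and plasma cell markers had a median of -0.03 with 2 lower when adjusted over the list alone. Markers of exocrine pancreas (median -0.02), adipose tissue (-0.07), skeletal muscle (-0.02), lung epithelium (0.02) and mesothelium, gall bladder and gut (-0.07) had no member past the threshold, and nor had hepatocyte markers (-0.11).

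Stress and housekeeping lists also gave no call over all animals. The 30 NRF2 genes had a median of -0.07, the 15 heat shock genes -0.08, the 24 unfolded protein response genes -0.05 and the 27 p53 genes -0.03. The 41 cytosolic ribosomal proteins had a median of -0.03, the 30 proteasome genes 0.01 and the 33 fatty acid oxidation genes 0.00. The 8 genes of the aryl hydrocarbon receptor battery had a median of -0.02, and the 12 metallothionein and metal handling genes 0.05.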
